A study of Mus musculus with 7 samples.

How the data were processed

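RNA sequencing of total RNA was made for 7 libraries of mouse CD8 T cells described as OT-I, 3 ACLY KO and 4 WT. The cells were taken 6 days after infection. Per the labels' protocols, RNA was isolated with a column kit that includes DNase digestion. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.0 and aligned with STAR 2.7.8 to mm10, and DESeq2 was used for differential expression, with no version stated. How reads were assigned to genes, the gene annotation, the strand setting and any filter are not given in the sources used here. The authors deposited a table of raw counts for 16156 genes in the 7 libraries and a table of log2 CPM of the same genes. The deposited log2 values equalled those recomputed here with edgeR from the deposited counts (TMM scaling, prior count 2) within 4.99e-09, and this table supplied the gene symbols.

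Values given as CPM were computed here from the counts with TMM scaling. The library totals are given at the start of the report. Before TMM scaling, a count of 3 equals 0.0397 CPM in the deepest library and 0.0801 CPM in the shallowest. Of the gene identifiers 16136 were found in GENCODE M21, which supplied coordinates, exons and the names of 2797 of the 2810 genes without a symbol. No library was left out. Pearson correlations of log2 CPM were 0.986 to 0.990 among WT replicates 1 to 3 and 0.929 to 0.936 between these and WT replicate 4. They were 0.877 to 0.897 among the KO libraries. KO replicates 2 and 3 correlated with WT replicates 1 to 3 at 0.898 to 0.911, above every pair of KO libraries. KO replicate 1 correlated with WT replicates 1 to 3 at 0.878 to 0.891, and the KO libraries with WT replicate 4 at 0.852 to 0.872.

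Genotypes were compared with R 4.3.3 and edgeR 4.0.16 (quasi-likelihood fit with its defaults, genotype as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05; filterByExpr removed 0 genes. Standard errors of log2 differences were derived from the same fit. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over 15 lists: fatty acid synthesis and acetyl-CoA supply, cholesterol synthesis, cytotoxic effector, memory and naive T cell, inhibitory receptors, cell cycle, glycolysis, TCA cycle, respiratory chain, fatty acid oxidation, histone acetyltransferases and deacetylases, type I interferon, ATF4 and amino acid stress, chemokine receptors and adhesion, and immediate early genes. Marker lists of 5 other cells were summed as CPM and compared by an exact permutation test of log2(sum + 1). In all 398 of 415 listed genes were measured. The comparison, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise; the tests of receptor shares were added later.

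The rule named Acly and Acss2; the 10 genes with the largest changes each way if enough passed, otherwise the 10 genes with the smallest unadjusted p, a mean log2 CPM of at least 1 and a proper symbol (1 unnamed model was skipped); in each of the 15 lists, where none passed, the 2 members with the smallest unadjusted p; and in each marker list the 2 members with the highest mean CPM. It gave 53 genes reported here, and 16 more were chosen after their values were seen. A few further genes are not reported here, and their places were not refilled. Of the 69, 12 share exons with another measured gene, so their counts are uncertain: Acss2, Amigo2, Cd3e, Csf1r, Cxcr5, Itga4, Lck, Lef1, Pfkp, Psph, St6gal1 and Xist. Reads of Hba-a1, Hbb-bs and the Trbv12 segments could be shared with near-identical copies.

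Alternatives were median-of-ratios and upper-quartile scaling, no filter, a mean count of 10 or more, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, a fold change threshold of 1.5, an estimated correlation and fry for the lists, a mean of log2(CPM + 1) for the markers, and each library left out in turn. Chosen after seeing the data were the bias-adjusted quasi-likelihood fit of edgeR, the removal of KO replicate 1 and WT replicate 4 together, Trbv12-1 alone, and leaving out libraries for the receptor shares and markers. The scripts were tested on simulated data of the KO against WT comparison. With the spread estimated from the 7 libraries (15631 genes), edgeR recovered 4 of 100 genes changed 2-fold and 51 of 100 changed 4-fold, with 6 false calls, and DESeq2 recovered 27 and 81, with 84 false calls. With a much smaller spread (15910 genes), edgeR recovered 85 and 98, with 8 false calls, and DESeq2 91 and 100, with 55 false calls.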

Results

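Messenger RNA levels were measured by RNA sequencing of total RNA from mouse CD8 T cells with and without ACLY. ACLY is ATP citrate lyase, the enzyme that splits citrate in the cytosol to make acetyl-CoA for lipid synthesis and protein acetylation. The transgenic T cell receptor of OT-I cells is of the V alpha 2 and V beta 5 families and recognises an ovalbumin peptide. The cells of this study were described as OT-I cells. They were transferred into C57Bl/6 mice 1 day before infection with Listeria monocytogenes that expresses ovalbumin, and were taken back 6 days after infection. There were 3 ACLY knockout (KO) libraries and 4 wild type (WT) libraries. The gene counts summed to 75586011, 45288353, 54667820 and 59238223 in WT replicates 1 to 4 and to 37820986, 39692359 and 37473484 in KO replicates 1 to 3, so every KO library was shallower than every WT library. The labels do not say whether the libraries of a genotype came from separate animals, so each p-value measures only the spread between these libraries.

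The single comparison asks how the transcripts of effector CD8 T cells differ without ACLY. Acly itself, which lies on the minus strand of chromosome 11 (start 100476353, end 100528000 in mm10), was checked first. It was at 393, 339, 414 and 276 CPM (counts scaled to library size) in WT replicates 1 to 4 and at 262, 62.0 and 209 CPM in KO replicates 1 to 3. Each KO library lay below each WT library, but KO replicate 1 was only slightly below WT replicate 4. The mean was 177 ± 103 CPM (SD, n = 3) in KO against 356 ± 61.4 CPM (SD, n = 4) in WT, a log2 difference of -1.0 ± 0.44 (SE). It did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.278). Without KO replicate 2 the log2 difference was -0.60. These are counts over the whole gene and do not show which exons were covered. Acss2, the enzyme that makes acetyl-CoA from acetate (chromosome 2, 155517948 to 155585724), was at 107 ± 37.2 CPM (SD, n = 3) in KO and 174 ± 50.8 CPM (SD, n = 4) in WT. The difference did not pass either (log2 -0.70 ± 0.33, SE; edgeR adjusted p = 0.315). Exons of Acss2 overlap those of Gss and Ggt7 on the other strand, so its level is uncertain.

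**Figure D1:**
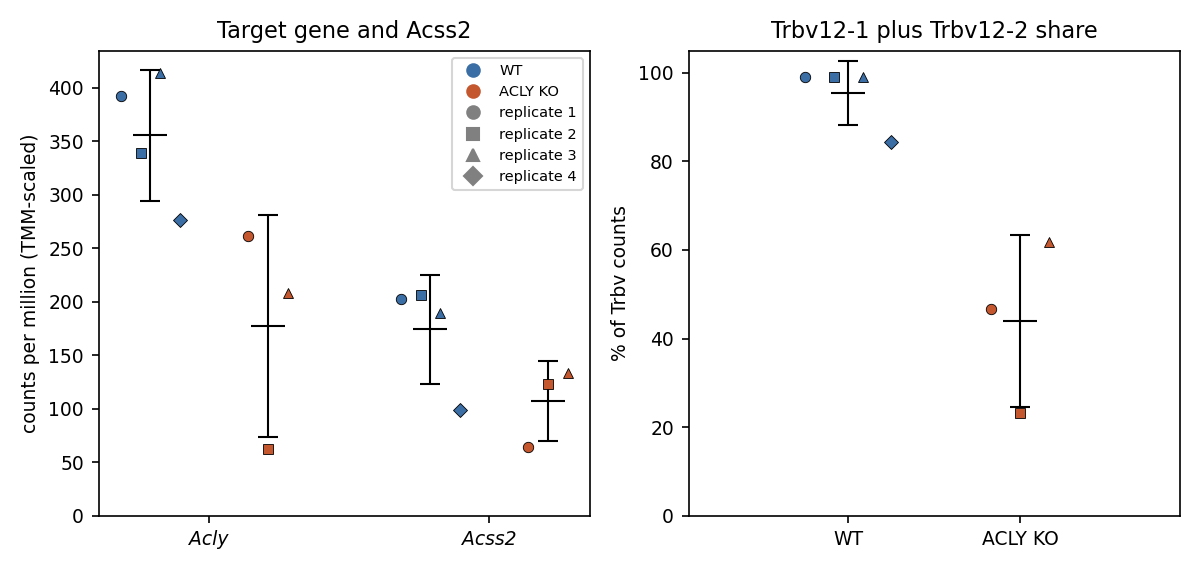
Left, CPM of Acly and Acss2 in each library (linear axis from 0); right, the percentage of all Trbv counts on Trbv12-1 and Trbv12-2. Each point is a library, marked by its replicate number, with mean and SD; KO replicate 2 has the lowest Acly level (62.0 CPM) and the lowest receptor share (23.2%).

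Each KO library held a smaller share of the OT-I receptor segments than any WT library. Trbv12-1 and Trbv12-2 are segments of the V beta 5 family, to which the V beta segment of the OT-I receptor belongs. Their joint share is called the OT-I receptor share here. They took 99.0%, 99.2% and 99.0% of all Trbv counts in WT replicates 1 to 3 and 84.5% in WT replicate 4 (95% exact Clopper-Pearson interval 84.0 to 84.9). They took 46.7% in KO replicate 1 (interval 45.6 to 47.8), 23.2% in KO replicate 2 (22.6 to 23.8) and 61.8% in KO replicate 3 (61.0 to 62.5), out of 8072 to 18479 Trbv counts. The mean share was 43.9% ± 19.4 (SD, n = 3) in KO and 95.4% ± 7.27 (SD, n = 4) in WT, a difference of -51.5 percentage points (exact permutation test, two-sided, p = 0.0286, the smallest that 35 splits can give; Benjamini-Hochberg adjusted p = 0.0571 with the Trav14 share below). Trbv12-1 alone took 40.9%, 8.59% and 56.3% in KO replicates 1 to 3 and 98.8%, 99.0%, 98.8% and 81.0% in WT replicates 1 to 4. Trbv12-2 took only 0.173% to 0.207% in WT replicates 1 to 3, but 5.85%, 14.6% and 5.43% in KO replicates 1 to 3. The joint share may therefore overstate the OT-I content of the KO libraries. In the KO libraries 14 to 17 of the 21 Trbv segments measured each held more than 1% of the Trbv counts, against 1 segment in WT replicates 1 to 3 and 6 in WT replicate 4. The share of Trav counts on the Trav14 segments of the V alpha 2 family was low in both genotypes, with 16.9% ± 4.74 (SD, n = 3) in KO and 14.9% ± 2.49 (SD, n = 4) in WT (exact permutation p = 0.486). Since WT replicates 1 to 3 held 99.0% or more on the V beta segments, the Trav14 share did not track the OT-I alpha chain here and says nothing of cell identity. These intervals cover counting error only, and Trbv12-1 and Trbv12-2 are closely related segments between which reads could be split. In WT replicates 1 to 3 no more than 0.207% of Trbv counts went to Trbv12-2, so such splitting was small there.

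Across all genes, the 10 named genes with the smallest p-values were all higher in each KO library than in any WT library, but none passed the adjusted threshold. Igfbp4, a binding protein of insulin-like growth factors (chromosome 11, 99041244 to 99054392), was at 181 ± 67.4 CPM (SD, n = 3) in KO and 6.34 ± 5.08 CPM (SD, n = 4) in WT (log2 4.83 ± 0.61, SE). WT replicate 4 was at 13.9 CPM, against 3.2 to 4.9 CPM in WT replicates 1 to 3, and without it the log2 difference was 5.57. Cyth3, an exchange factor of ARF GTPases (chromosome 5, 143622447 to 143710250), was at 46.4 ± 10.7 CPM in KO and 7.98 ± 1.5 CPM in WT (SD, n = 3 and n = 4), or 5.82-fold higher. Trio, a nucleotide exchange factor, Eef2k, the kinase of elongation factor 2, Ggt5, a gamma-glutamyl transferase, and Amigo2, an adhesion protein, were 9.59, 7.03, 7.69 and 9.75-fold higher. St6gal1, a sialyltransferase, was at 99.3 ± 45.5 CPM in KO (SD, n = 3) and 10.1 ± 3.23 CPM in WT (SD, n = 4). Slpi, a secreted protease inhibitor, Nfam1, a receptor with an activation motif, and Tlr7, a sensor of single-stranded RNA, were 50.8, 89.9 and 159-fold higher, with 0.686, 0.422 and 0.0956 CPM in WT. Without KO replicate 1 the log2 difference went from 5.67 to 4.88 for Slpi and from 6.49 to 5.44 for Nfam1, which was at 77.5, 14 and 22.9 CPM in KO replicates 1 to 3. The adjusted p of each of the 10 genes was 0.0651. B cell and antigen presentation transcripts, described further on, were also higher in the KO libraries.

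Of 16156 genes tested, edgeR's quasi-likelihood test called 0 higher and 0 lower in KO at an adjusted p under 0.05. At an unadjusted p under 0.05 it counted 1770 higher and 1275 lower, where 808 in all are expected by chance. DESeq2 called 1032 higher and 520 lower, and limma voom with quality weights called 860 higher and 272 lower. The KO libraries lay wholly above the WT libraries for 9.46% of genes and wholly below for 9.03%, where chance gives 2.86% each way. Without KO replicate 1 edgeR called 111 higher and 48 lower, without KO replicate 2 it called 118 and 2, without KO replicate 3 142 and 47, and without WT replicate 4 108 and 21. Without both KO replicate 1, which held the most transcripts of other cells, and WT replicate 4, which held the most cell cycle transcripts, it called 864 higher and 668 lower, a choice made after seeing the data.

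**Figure D2:**
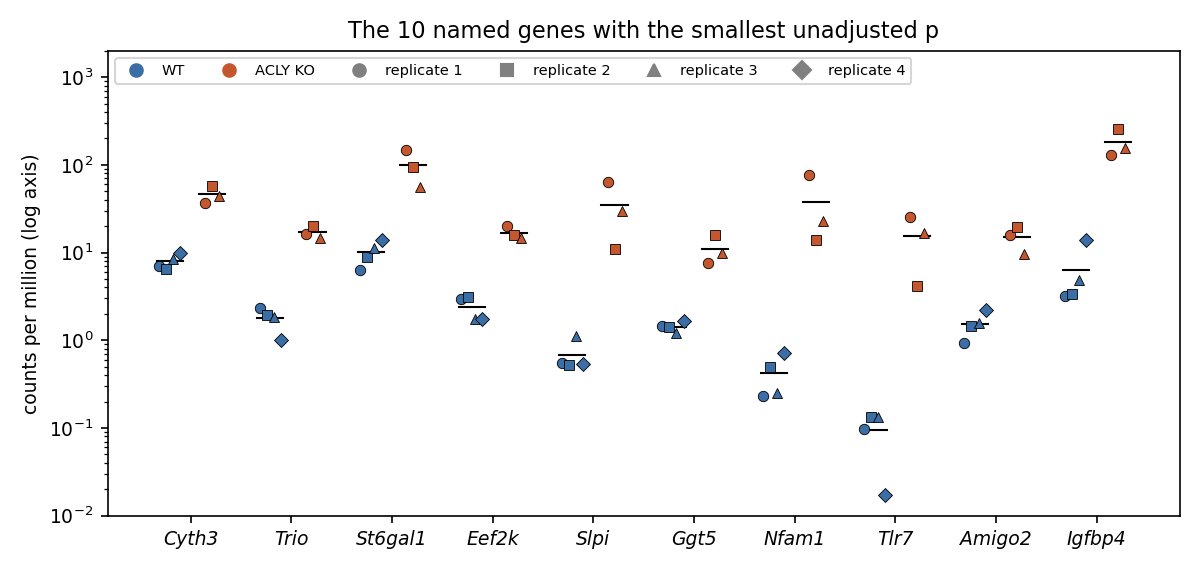
CPM (log axis) of the 10 named genes with the smallest unadjusted p, per library, with lines at the group means. In each gene the 3 KO libraries lie above the 4 WT libraries; the difference of none passed an edgeR adjusted p of 0.05, each having 0.0651.

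The cytotoxic effector list, with granule proteins, effector chemokines and the regulators of effector cells, was lower in KO, with 21 of 23 measured members below 0 and a median log2 difference of -1.0. Tbx21, which encodes the effector regulator T-bet, was at 249 ± 124 CPM (SD, n = 3) in KO and 612 ± 57.4 CPM (SD, n = 4) in WT, with each KO library below each WT library. Tnf, a cytokine of the same list, went the other way: it was at 14.4 ± 3.90 CPM (SD, n = 3) in KO and 5.34 ± 1.83 CPM (SD, n = 4) in WT. Gzmb, Nkg7, Ccl5 and Klrg1 were chosen after their values were seen. Gzmb (granzyme B) was at 94.6 ± 56.9 CPM in KO and 243 ± 63.0 CPM in WT (SD, n = 3 and n = 4). Nkg7, a granule protein, was at 1170 ± 551 and 2541 ± 54.1 CPM. The chemokine Ccl5 was at 2054 ± 1183 and 5512 ± 1900 CPM. Klrg1, a marker of terminal effector cells, was at 89.2 ± 44.7 and 230.2 ± 154 CPM (SD, n = 3 and n = 4). In WT replicate 4 Klrg1 was at 31.7 CPM, below every KO library (48.2, 82.7 and 137 CPM). Gzmb and Ccl5 in WT replicate 4 (156 and 2703 CPM) were below KO replicate 3 (159 and 3420 CPM). Nkg7 was lower in each KO library than in any WT library. limma camera with a preset correlation of 0.01 called the list lower (adjusted p = 0.00143), but with an estimated correlation the call was lost (adjusted p = 0.687). No member passed over all genes tested in edgeR, 1 higher and 7 lower passed when adjusted over the list alone, 1 higher and 7 lower had an unadjusted p under 0.05, and DESeq2 called 1 higher and 7 lower. WT replicate 4 had a mean of 6.06 log2 CPM over the list, close to the 5.77, 5.94 and 6.77 of KO replicates 1 to 3, against 7.08 to 7.26 in the other WT libraries.

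Genes of memory and naive T cells were higher in KO, with 18 of 22 members above 0 and a median log2 difference of 0.63. Igfbp4, given above, belongs to this list. Ccr7, the lymph node homing receptor, was at 178, 798 and 600 CPM in KO replicates 1 to 3 and 112 ± 13.7 CPM (SD, n = 4) in WT. Lef1, a transcription factor of naive T cells, was at 268, 767 and 593 CPM and 275 ± 37.9 CPM (SD, n = 4). Both were chosen after their values were seen. camera called the list higher (adjusted p = 0.00163), with an adjusted p = 0.662 for an estimated correlation, and without KO replicate 2 the list was not called (adjusted p = 0.0549). No member passed over all genes in edgeR, 6 higher and 0 lower passed when adjusted over the list alone, 9 higher and 1 lower had an unadjusted p under 0.05, and DESeq2 called 9 higher and 0 lower. Beside both lists stand the lower OT-I receptor share of the KO libraries (43.9% against 95.4%) and their B cell marker sums of 1955 to 31149 CPM against 301 to 711 CPM in WT. Most of each WT sum was the single gene Ighm.

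Respiratory chain and fatty acid oxidation genes were slightly lower in KO as lists, while the TCA cycle list was not called. In the respiratory chain list 24 of 25 members were below 0 (median log2 -0.46), and 15 lay below every WT library in every KO library, where 9.03% of all genes did. Ndufa1 and Ndufa4, subunits of the chain, were at 68.8 ± 7.07 and 122 ± 17.0 CPM in KO (SD, n = 3) and 135 ± 27.1 and 232 ± 52.2 CPM in WT (SD, n = 4). In fatty acid oxidation 16 of 17 members were below 0 (median log2 -0.26). Ech1, an enoyl-CoA isomerase, was at 114 ± 2.54 CPM in KO (SD, n = 3) and 196 ± 18.9 CPM in WT (SD, n = 4; log2 -0.78 ± 0.12, SE). Hadha, a subunit of the trifunctional protein, was at 81.9 ± 7.39 and 112 ± 5.11 CPM. camera called both lists lower (adjusted p = 4.14e-06 and 0.00844), with adjusted p = 0.662 and 0.639 for an estimated correlation. Over all genes no member of either list passed in edgeR. When adjusted over the list alone 7 respiratory chain and 2 oxidation genes passed, all lower, 14 and 3 had an unadjusted p under 0.05, and DESeq2 called 7 and 3. The oxidation list was not called without KO replicate 2 (adjusted p = 0.0502), nor without both KO replicate 1 and WT replicate 4 (adjusted p = 0.0772). The lower OT-I receptor share and the higher B cell and myeloid marker sums of the KO libraries stand beside these lists as well. The TCA cycle list was not called (adjusted p = 0.132, 19 of 25 members below 0, 1 lower when adjusted over the list alone). Sucla2, a subunit of succinyl-CoA synthetase, was at 78.5 ± 6.43 CPM in KO and 122 ± 11.1 CPM in WT. Pdk1, the kinase that inhibits pyruvate dehydrogenase, was at 255 ± 124 and 110 ± 16.2 CPM. Glycolysis was not called (adjusted p = 0.138, 14 of 18 members below 0, 0 when adjusted over the list alone, 2 lower at an unadjusted p under 0.05, 0 by DESeq2), except without KO replicate 3 (adjusted p = 0.044). Slc2a3, a glucose transporter, was at 115 ± 53.2 CPM in KO and 197 ± 21.2 CPM in WT. Pfkp, a phosphofructokinase, was at 303 ± 109 and 454 ± 32.1 CPM.

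Neither list of lipid synthesis genes was called. In fatty acid synthesis and acetyl-CoA supply 11 of 17 members were below 0 and 6 above; the median log2 difference was -0.05 and the mean 0.59, and camera gave an adjusted p of 0.655 in the downward direction. Fasn, the fatty acid synthase, chosen after its values were seen, was at 161 ± 50.8 CPM in KO (SD, n = 3) and 167 ± 26.5 CPM in WT (SD, n = 4). Its sign turned with the normalization and the libraries used, from log2 -0.05 to 0.01 with upper-quartile scaling. Scd1, a desaturase, was at 247, 3.89 and 0 CPM in KO replicates 1 to 3, and at 0.161 ± 0.141 CPM (SD, n = 4) in WT. The count of 0 in KO replicate 3 allows up to 0.0801 CPM (3 counts, before TMM scaling). Acsl3, a long-chain acyl-CoA ligase, was at 13.3, 2.40 and 1.54 CPM in KO replicates 1 to 3 and 0.797 ± 0.605 CPM (SD, n = 4) in WT. In cholesterol synthesis 15 of 24 members were below 0, with a median log2 difference of -0.12, a mean of 0.06 and a camera adjusted p of 0.655 in the downward direction. This list pointed upward without WT replicate 4, without KO replicate 2, with the replicate block, and without both KO replicate 1 and WT replicate 4. The fatty acid list pointed upward without KO replicate 1, and without both. Neither was called in these settings. Acat2, an acetyl-CoA acetyltransferase, was at 27.6 ± 2.31 CPM in KO (SD, n = 3) and 44.1 ± 6.18 CPM in WT (SD, n = 4). No member of either list passed over all genes or when adjusted over the list alone, and DESeq2 called 1 higher in fatty acid synthesis and 1 higher and 1 lower in cholesterol synthesis.

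Chemokine receptors, adhesion and residency genes were lower in KO as a list, with 13 of 19 members below 0 and a median log2 difference of -0.74. Cxcr6, a chemokine receptor, was at 225 ± 102 CPM in KO (SD, n = 3) and 703 ± 247 CPM in WT (SD, n = 4). Itga4, an integrin chain, was at 311 ± 148 and 829 ± 89.4 CPM. Its partner Itgb1, chosen after its values were seen, was at 1260 ± 862 and 4482 ± 1184 CPM. camera called the list (adjusted p = 0.0106; 0.662 with an estimated correlation), but not without KO replicate 1 (adjusted p = 0.169), nor without both KO replicate 1 and WT replicate 4 (adjusted p = 0.545). In this list 4 members passed when adjusted over the list alone, all lower, 8 had an unadjusted p under 0.05, and DESeq2 called 5. The lower OT-I receptor share and the higher B cell and myeloid marker sums of the KO libraries stand beside this list too. Immediate early genes, which T cells turn on within minutes of stimulation, were not called (camera adjusted p = 0.12), with 1 higher when adjusted over the list alone, 6 higher at an unadjusted p under 0.05 and 4 higher by DESeq2. Without KO replicate 1, without WT replicate 3, or without both KO replicate 1 and WT replicate 4 camera called them higher (adjusted p = 0.00128, 0.00571 and 0.0151). Egr3, an early growth response factor, was at 43.0, 14.3 and 1.79 CPM in KO replicates 1 to 3 and 0.96 ± 0.559 CPM (SD, n = 4) in WT. Myc was at 224 ± 92.1 CPM (SD, n = 3) and 95.8 ± 33.6 CPM (SD, n = 4). In the type I interferon list 17 of 24 members were above 0 (camera adjusted p = 0.129), and 4 higher and 1 lower passed when adjusted over the list alone; it was called without KO replicate 3 (adjusted p = 0.0161). Oasl2, an interferon-induced gene, was at 23.7, 25.9 and 4.25 CPM in KO replicates 1 to 3 and 1.45 ± 0.703 CPM (SD, n = 4) in WT. Isg20, an exonuclease, was at 239, 50.3 and 11.6 CPM and 9.0 ± 2.27 CPM.

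All 32 cell cycle genes were below 0 (median log2 -1.26), but camera did not call the list (adjusted p = 0.13). WT replicate 4 stood apart: its mean over the list was 7.55 log2 CPM, against 3.72 to 3.94 in the other WT libraries and 5.65, 4.04 and 2.97 in KO replicates 1 to 3. Mcm6, a subunit of the replicative helicase, was at 292, 279, 329 and 589 CPM in WT replicates 1 to 4 and 218 ± 46.1 CPM (SD, n = 3) in KO, so each KO library lay below each WT library. Tyms, thymidylate synthase, was at 33.8, 43.5, 35.1 and 146 CPM in WT and 24.3 ± 11.3 CPM (SD, n = 3) in KO. Leaving out WT replicate 1, WT replicate 2, WT replicate 3 or KO replicate 1 brought a downward call of the list (adjusted p = 0.0149, 0.0157, 0.0233 and 0.0453). The direction rested on WT replicate 4: without it the list pointed upward (adjusted p = 0.329), as it did with the replicate block, which leaves it out too (adjusted p = 0.22). Without KO replicate 1 and WT replicate 4 the median log2 difference was -0.09. Inhibitory receptors were not called (adjusted p = 0.403, 8 of 15 below 0). Lag3 was at 4.58 ± 2.90 CPM in KO (SD, n = 3) and 15 ± 0.559 CPM in WT (SD, n = 4). Cd160 was at 52.3 ± 38.4 and 167 ± 73.2 CPM. The ATF4 and amino acid stress list was not called (adjusted p = 0.57). Psph, an enzyme of serine synthesis, was at 40.1 ± 3.46 CPM in KO and 62.7 ± 3.76 CPM in WT. Slc7a5, an amino acid transporter, was at 73.1 ± 27.7 and 42.4 ± 8.97 CPM. Histone acetyltransferases and deacetylases were not called (adjusted p = 0.655; median log2 -0.10, mean 0.23). Sirt1 was at 36.5 ± 2.85 CPM in KO and 50.7 ± 3.78 CPM in WT. Hdac9 was at 31.5, 0.722 and 0.819 CPM in the KO libraries and 0.276 ± 0.307 CPM in WT. In these 4 lists 1 member passed when adjusted over the list alone, a lower gene of the ATF4 list, and no member passed over all genes in edgeR. DESeq2 called 3 inhibitory receptor genes, 1 ATF4 gene and 1 histone acetyltransferase or deacetylase gene lower and 0 cell cycle genes. At an unadjusted p under 0.05 edgeR counted 1 higher and 3 lower, 1 and 1, 3 and 2, and 0 and 1 in these lists.

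**Figure D3:**
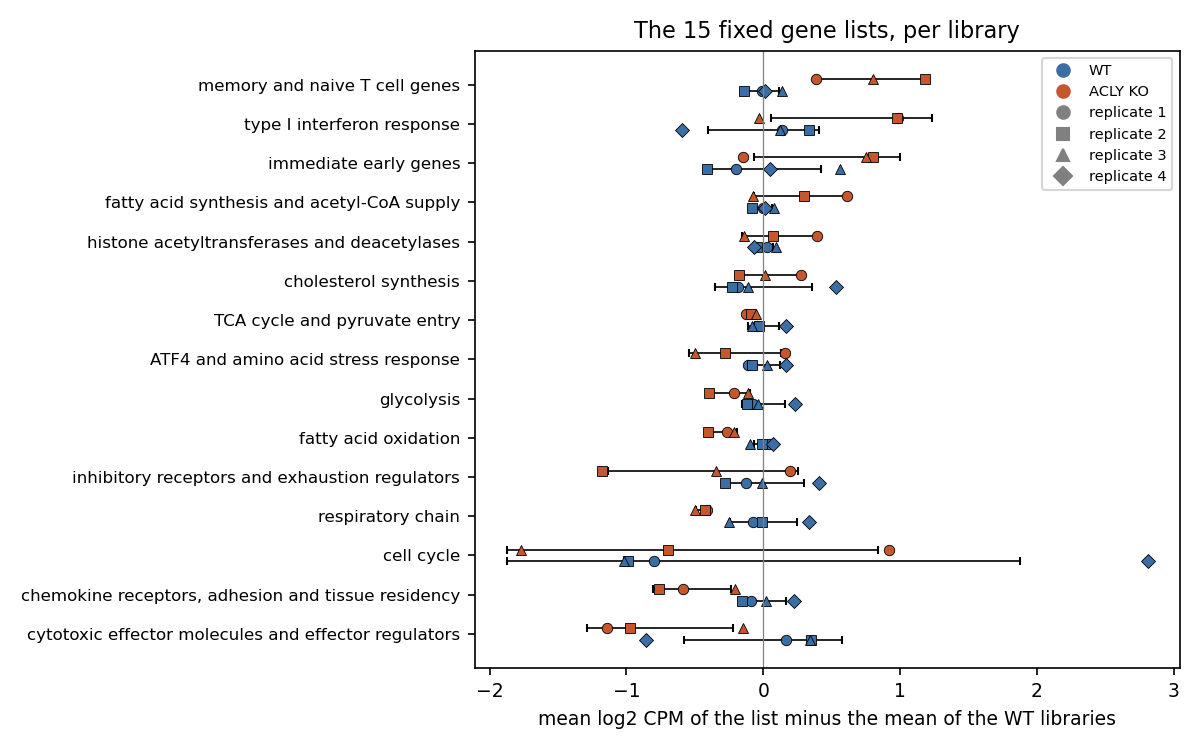
Mean log2 CPM of each of the 15 fixed gene lists in each library, minus the mean of the WT libraries, with group mean and SD (bars). The KO libraries all lie above the WT libraries for the memory and naive list and all below for the respiratory chain, fatty acid oxidation and chemokine receptor and adhesion lists; WT replicate 4 stands apart for the cell cycle, effector and cholesterol synthesis lists.

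B cell and myeloid markers were more abundant in each KO library than in any WT library, though neither list passed its test. The B cell and antigen presentation list summed to 31149, 2117 and 1955 CPM in KO replicates 1 to 3 and to 301 to 711 CPM in the WT libraries, and 12 of its 14 genes were higher in each KO library than in any WT library. Cd74, the invariant chain of MHC class II, was at 11072, 398 and 769 CPM in KO replicates 1 to 3 and 13.3 ± 7.14 CPM (SD, n = 4) in WT. Ighm, the immunoglobulin mu chain, was at 3745, 939 and 545 CPM and 381 ± 194 CPM. It overlapped between genotypes and, at 303, 224, 332 and 664 CPM in WT replicates 1 to 4, made up most of each WT sum. The WT sums therefore say little of the other B cell genes. Myeloid markers summed to 2132, 115 and 1062 CPM in KO and 42.5 to 59.7 CPM in WT. Lyz2 (lysozyme) was at 725, 21.2 and 38.9 CPM and 2.57 ± 3.31 CPM. Csf1r, the receptor of a macrophage growth factor, was at 150, 4.12 and 239 CPM and 2.56 ± 1.18 CPM. Erythroid markers summed to 47390, 6577 and 238 CPM in KO and 1.67 to 476 CPM in WT. Hbb-bs was at 26764, 3683 and 142 CPM and Hba-a1, whose reads a near-identical copy could share, at 9180, 1638 and 58.1 CPM in KO replicates 1 to 3. The sums of CD4 T cell and NK cell markers overlapped between genotypes, with 489, 100 and 178 CPM and 85.9, 63.2 and 91.1 CPM in KO replicates 1 to 3 against 124 to 217 and 64.6 to 149 CPM in WT. Of these markers, 3 of 6 CD4 T cell and 3 of 8 NK cell genes were higher in each KO library than in any WT library. The mean log2 CPM of the CD4 T cell list was also higher in each KO library (2.23 to 5.01) than in any WT library (1.0 to 1.93). Most of the CD4 T cell sum in each WT library was Icos, so the sum mainly follows that gene. Cd4 itself, chosen after its values were seen, was at 110, 1.19 and 6.19 CPM in KO replicates 1 to 3 and at most 0.157 CPM in WT. The most abundant genes of these lists were Icos, at 97.0 ± 28.7 CPM in KO and 144 ± 29.6 CPM in WT, and Cxcr5, at 202, 23.9 and 26.0 CPM in KO replicates 1 to 3, for CD4 T cells. For NK cells they were Gzmm, at 28.7 ± 16.8 CPM in KO and 47.2 ± 5.01 CPM in WT, and Klrb1c, at 19.1 ± 5.32 CPM in KO and 50 ± 33.1 CPM in WT. None of the 5 lists passed the exact permutation test after Benjamini-Hochberg adjustment (adjusted p = 0.0714 for the B cell and myeloid lists, each with p = 0.0286, and 0.143, 0.286 and 0.8 for erythroid, NK and CD4 T cell markers), and 35 splits cannot give a smaller p than 0.0286. The CD8 T cell identity genes were all 12 below 0 (median log2 -0.46). Ptprc (CD45) was at 2639 ± 456 CPM in KO (SD, n = 3) and 3802 ± 929 CPM in WT (SD, n = 4). Lck, a kinase of receptor signalling, was at 1759 ± 691 and 2240.2 ± 391 CPM. Cd3e, a chain of the T cell receptor complex chosen after its values were seen, was at 453, 882 and 948 CPM in KO replicates 1 to 3 and 956 to 1162 CPM in WT.

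**Figure D4:**
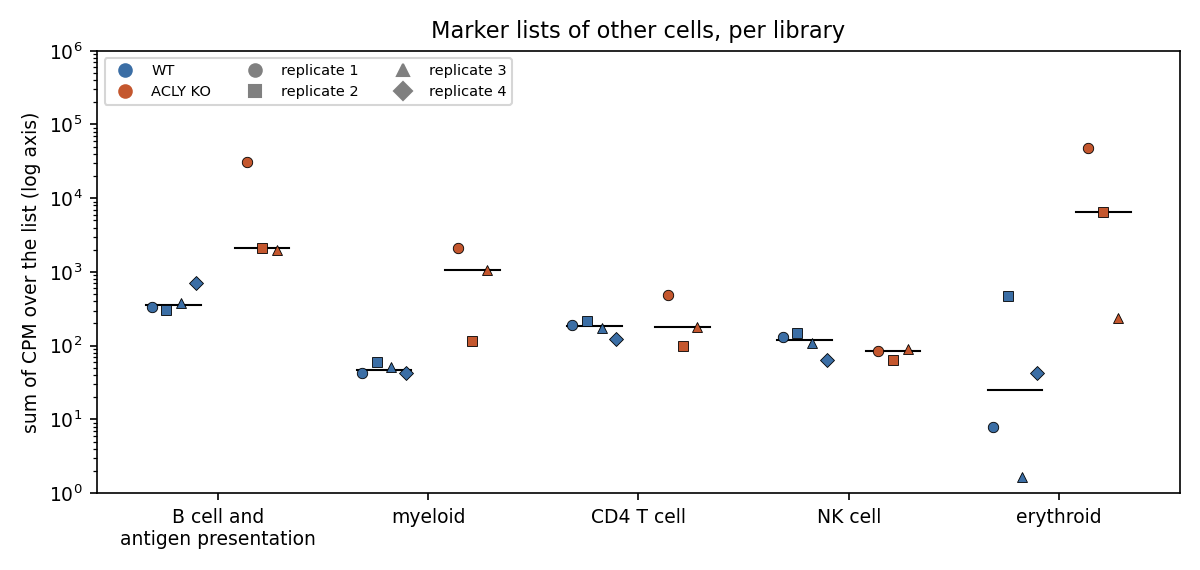
Sum of CPM over each marker list of other cells (log axis), per library, with lines at the group medians. KO replicate 1 has the highest B cell (31149 CPM), myeloid (2132 CPM), CD4 T cell (489 CPM) and erythroid (47390 CPM) sums.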

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

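The tests that scale genes to receptor or Cd3 transcripts and the comparison of marker genes between KO replicates 1 and 3 were chosen only after the result was seen. In 19 of 93 results examined, 1 of the 4 WT libraries lay far from the other 3, where chance would give about 1 in 20 (4.65). In 13 of the 19 it was WT replicate 4. Many of these results share a signal, such as the cell cycle list with Mki67, Top2a, Mcm6 and Tyms. Mki67, Top2a, Xist and S100a8 were also chosen after their values were seen. The size of the excess over 4.65 therefore cannot be judged. The values here are the gap to the nearest library divided by the range. For WT replicate 4 they were 0.943 for the cell cycle list, 0.846 for the effector list, 0.851 for cholesterol synthesis, 0.985 for the OT-I receptor share, 0.982 for Mki67 (340 CPM against 16.6 to 22.5), 0.994 for Top2a, 0.84 for Mcm6, 0.913 for Tyms, 0.848 for Acss2, 0.841 for Igfbp4, 0.909 for Acat2, 0.988 for Trbv12-2 and 0.858 for Xist. For WT replicate 3 they were 0.942 for Slpi and 0.925 for Psph. For WT replicate 2 they were 0.921 for Lyz2, 0.92 for Hbb-bs, 0.904 for Hba-a1 and 1 for S100a8 (0.224 CPM against 0).

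B cell, myeloid and erythroid transcripts in the KO libraries could come from such cells or from expression inside the T cells. The test fixed in advance counted immunoglobulin V segments with 10 or more counts, and it did not separate the genotypes: KO replicates 1 to 3 held 32, 26 and 13 segments and WT replicate 2 held 19, a difference of -6 between the lowest KO and the highest WT library. As written, this outcome counts against B cells in every KO library, but it is smaller than the SD of 8.66 among the WT libraries. These segments summed to 1076, 30.8 and 9.26 CPM in KO replicates 1 to 3 and to 0.678 to 11.7 CPM in WT, so KO replicates 1 and 2 lay above every WT library and KO replicate 3 did not. The origin in KO replicate 3 is left open, a reading made after the result was seen. Reads carried over from KO replicate 1 are not a sufficient account of the myeloid transcripts in KO replicate 3. There 7 myeloid marker genes, among them C1qa (117 against 47.9 CPM) and Csf1r, were higher than in KO replicate 1. All B cell and erythroid markers were lower in KO replicate 3 than in KO replicate 1 (Cd74 769 against 11070 CPM). KO replicate 2 was not compared, so carry-over stays open for that library and for these markers.

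Segments other than Trbv12-1 held 59.1%, 91.4% and 43.7% of Trbv counts in KO replicates 1 to 3. They held 0.994% to 1.23% in WT replicates 1 to 3 and 19.0% in WT replicate 4. The KO libraries thus held many receptor transcripts of T cells other than OT-I cells. Whether such T cells account for the lower effector and higher memory and naive genes is not known. Scaling to Trbv12-1 cannot test this: Trbv12-1 was itself lower in KO (log2 -2.30), more than the effector list, so the scaled list had to turn positive (median log2 difference 1.70). Dilution by RNA of cells that are not T cells was tested by scaling to Cd3d, Cd3e and Cd3g. The effector list then differed by only -0.16 (exact permutation p = 0.6, WT SD 0.523), but without WT replicate 4 by -0.41 (WT SD 0.187). The latter came mainly from KO replicate 2. The scaled means were -2.67, -3.52 and -2.78 in KO replicates 1 to 3 and -2.79 to -2.44 in WT replicates 1 to 3. KO replicates 1 and 3 thus lay within the range of those WT libraries. Whether dilution could give the lower effector list stays open. For 6 naive genes (Lef1, Tcf7, Dapl1, Igfbp4, Satb1 and Actn1) the scaled mean was 2.01 higher in KO. These genes were picked after the result was seen, from a list already higher in KO, while Cd3e was lower (log2 -0.46). A positive value was therefore largely fixed in advance and is no separate test. Dilution by cells that lack these genes would lower them, so it alone does not give higher levels. Whether the other cells lack them was not tested. An effect of ACLY on the OT-I cells themselves cannot be told apart from these mixtures.

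Lower respiratory chain genes could follow transcript length or a loss of short transcripts. After removal of a length trend the median log2 difference was -0.36 (SE over the 25 member genes 0.0474). Ribosomal protein genes, which are also short, had a median of -0.22 (SE over 79 genes 0.0306). These SEs treat genes of the same libraries as independent and do not measure the spread between libraries. By the medians alone neither accounts for the whole difference, but whether this holds beyond the spread between libraries was not tested. A shift about as large as that of the ribosomal protein genes is not specific to the chain.

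Other splits of the 7 libraries into 3 and 4 were tried. No split gave a gene past the adjusted threshold by edgeR; with a real count of 0 all 35 of 35 give as many whatever the data, so this tells nothing about chance. At an unadjusted p under 0.05 only 1 of 35, the real split, gave as many as 3045 genes; the next, WT replicates 1 to 3 against the rest, gave 2627. For lists, 15 of 35 splits gave at least the real 5 calls, and another split gave 11, so the number of lists called could arise without any effect of genotype. Genes within 5 Mb of Acly passed an unadjusted p of 0.05 no more often than others (17.7% against 18.9%, one-sided Fisher exact p = 0.686).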

How the results depend on the processing

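The receptor share and the markers without single libraries, Trbv12-1 alone, the bias-adjusted fit and the removal of KO replicate 1 and WT replicate 4 together were chosen after seeing the data. edgeR called 0 genes with either other scaling, the mean count filter or the replicate block; removing the filter changed nothing, and a fold change threshold cannot raise a count of 0. Calls higher and lower were 1032 and 520 with DESeq2, 860 and 272 with voom, 497 and 77 with the bias-adjusted fit, and 864 and 668 without KO replicate 1 and WT replicate 4; without single libraries they ran from 0 to 142 and from 0 to 48. Of 1532 calls without both libraries, 677 were also called by DESeq2, all in the same direction. Both fits used KO replicates 2 and 3 and WT replicates 1 to 3, so a shared direction was nearly fixed in advance and tells little. Acly stayed lower in all these settings, passing only with voom (log2 -1.48, adjusted p = 0.0449), and from -1.39 to -0.60 without single libraries. No list was called with an estimated correlation (0) and 1, fatty acid oxidation, with fry; 3 to 7 were called without single libraries and 4 without both. The difference in OT-I receptor segments was -59.1 for Trbv12-1 alone and from -60.4 to -41.2 without single libraries, where the exact p of 0.1 or 0.0667 is the smallest such designs allow. No marker list passed (0) with the mean of log2(CPM + 1); with libraries left out none could, for the same reason. Of 68 other named genes, 55 passed in some setting and 4 changed sign: Mki67 with the block (0.012) and without single libraries (-2.98 to 1.20), Top2a without single libraries (-2.81 to 0.16), Fasn with upper-quartile scaling (0.0084), voom (0.026), both libraries out (0.19) and without single libraries (-0.34 to 0.11), and Xist with voom (0.22), the block (0.13), both out (0.95) and without single libraries (-0.53 to 0.47). Replicate numbers are not known to be pairs, and deviations of same-number libraries correlated at -0.108, -0.0513 and 0.137. Apart from fewer libraries, the cause was not tested. A simulation recovered 4 of 100 genes changed 2-fold, so a count of 0 does not exclude such changes.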

Other observations

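The receptor repertoire of the KO libraries was broad. In KO replicate 2 the leading segments were Trbv12-2 (14.6% of Trbv counts), Trbv16 (12.5%) and Trbv12-1 (8.59%), against 98.8% or more on Trbv12-1 in WT replicates 1 to 3. KO replicate 2 also had the lowest Acly (62.0 CPM). Relative to T cell transcripts, a scale chosen after the result was seen, Acly was not lower in every KO library. Scaled to Cd3d, Cd3e and Cd3g, it was at log2 -0.44, -3.52 and -1.86 in KO replicates 1 to 3 and -1.56 to -1.04 in WT (difference -0.61, exact permutation p = 0.571), so KO replicate 1 lay above every WT library. That library also had the highest B cell, myeloid and erythroid sums (31149, 2132 and 47390 CPM) and the lowest Cd3e (453 CPM), while Acly is counted over all cells. Scaled to Trbv12-1, Acly was at 1.56, 0.74 and -0.30 in KO and -1.28 to -0.36 in WT, but Trbv12-1 was lower in KO by more than Acly (log2 -2.30), so this ratio had to rise and tests nothing.

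Genes of the sex chromosomes, chosen after their values were seen, differed between libraries. Ddx3y, on the Y chromosome, was at 117 CPM in KO replicate 1, 4.61 in KO replicates 2 and 3 and 0.749 to 4.78 in WT. Xist, made from the inactive X chromosome, was at 6.12, 32.3 and 38.9 CPM in KO replicates 1 to 3 and 16 to 54.7 CPM in WT. Cd4 was at 110, 1.19 and 6.19 CPM in KO replicates 1 to 3 and at most 0.157 CPM in WT.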
